A study of Mus musculus with 3 samples.

How the data were processed

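RNA from untreated wild-type cortical neurons of embryonic mice, kept in neurobasal medium with B27, was sequenced in 3 libraries of 1 group, per the labels' protocols. The same protocol text describes etoposide, a TOP2 poison, but the labels of these libraries give no treatment. Libraries were made with a strand-specific kit from poly-A RNA, per the labels' protocols. The deposited table gives TPM for each transcript and library, computed by the authors, per the file headers. Trimmomatic, TopHat, Bowtie and HTSeq and the mm10 build are named per the submitters' processing notes, with no versions, role or order. The annotation the authors used was GENCODE, as the deposited table is named for its release. The strand setting, the treatment of reads that map to several places and any filter on transcripts are not given in the sources used here.

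The table holds 84660 transcript rows, 5556 of them at 0 in all libraries, and each library sums to 1000000. Transcript identifiers were matched, without version, to GENCODE release M21, which uses the same genome build: 83017 rows matched, 30 of these lay elsewhere in M21 and were given no gene, and 1643 did not match. Gene symbols and types are those of M21, and coordinates are those of the deposited rows, written from base 1. The result was 27494 genes, 18221 of them protein-coding.

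The depth was recovered from the values. For 42156 rows whose model is equal in both annotations, TPM times exonic length was a whole multiple, within 0.01, of 1 number per library in 100% of rows, so reads per row could be computed. The reads of each gene's fullest row add up to at least 26.9, 23.8 and 23.4 M in libraries 1, 2 and 3. Counts were used only for depth and to compare replicates, because TPM was deposited and no groups exist. Over 13634 to 13746 genes the chi-square per degree of freedom between library pairs was 11.1, 15.7 and 17.0, far above sampling noise, and no row above 0 was identical in a pair, so all 3 libraries were kept.

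Transcript rows of a gene share reads. In 777 pairs in which each exon of a transcript of at least 300 bases lies within those of a longer transcript of the gene with at least 100 reads, the shorter row had a median of 1.30 times the TPM of the longer, none was at 0, and in 99.1% the longer row had at least as many reads. Before the data were examined, the gene value was set as the sum over transcripts, with the highest transcript as the alternative. Because a sum counts shared reads repeatedly, the roles were exchanged: the gene value is the transcript with the highest mean TPM, the sum is an alternative, and the longest transcript (longest coding transcript of protein-coding genes) was added after seeing the data. The highest transcript is often a short or non-coding model, as for Top2b, and overstates genes with such models. In 4 cases a transcript lay wholly within exons of a transcript of at least 50 TPM on the other strand; its TPM was a median of 0.00081 times that level, as counting by strand would give.

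A gene was called detected at a mean TPM of at least 1. Log values are log2(TPM + 1), which understates ratios of low genes. Before the data were examined, 33 gene lists with 487 symbols were fixed, of which 480 symbols were in the table, 5 under another symbol; 6 genes are in more than 1 list. Each list's median was placed among the medians of 10000 random lists of the same size drawn from protein-coding genes, as a description of these libraries. Differences between genes or lists were taken within each library and tested with an exact two-sided sign-flip permutation over libraries, which cannot give a p below 0.25 with 3 libraries. Genomic span runs from the first to the last base of a gene's rows.

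Named genes are members of the lists, the 25 highest protein-coding genes, the 25 highest of those over 200 kb, the 10 with the largest coefficient of variation at 10 TPM or more, and the 10 highest genes of the lincRNA, antisense and processed transcript types. Mir6236 and the pairs of paralogs were chosen after their values were seen. For each gene's longest transcript the share of its 50-base words, on either strand, that occur at no other annotated locus of M21 was computed; loci join genes whose spans overlap, and unannotated sequence was not searched.

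Alternatives were leaving out each library, the sum and the longest transcript, a pseudocount of 0.1, detection at 0.5 and 5 TPM, the median over libraries, scaling to nuclear protein-coding genes, random lists matched on span, restriction to detected genes or to genes with at least 90% unique words, and list means. The calculations were tested on simulated data: reads drawn for 42156 rows were recovered in 100% of rows in libraries 1, 2 and 3, 5.05% of 2000 unchanged lists of 15 genes reached the 95th percentile and 71.8% of lists raised by 2 log2 units did, and a simulated rho of 0.2 over 18221 genes was returned as 0.205. The list test replaced a coarser first version, with fewer lists and draws, in which more than 5% of unchanged lists passed. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Rows without a matched gene and small RNA genes entered no comparison.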

Results

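Poly-A selected RNA was sequenced from cultured cortical neurons of embryonic Swiss-Webster mice, an outbred stock. The data comprised 3 libraries of 1 group, wild-type neurons that received no drug, and there was no other group to compare them with. The series belongs to a study that maps where the type II topoisomerase TOP2B is at work in the neuronal genome, and these libraries give the expression background of such maps. The comparisons below are therefore between genes and gene lists within the same libraries. Values are TPM, a length-scaled share of reads, of the highest transcript row of each gene, given as mean ± SD of the libraries (n = 3). A list's median is that of log2(mean TPM + 1) over its members, and its SD is that of the 3 library medians. The mean of those library medians can differ from it. For 75 of 368 detected genes of the lists this row was at least 1.5 times the longest transcript, so single levels are approximate. At least 26.9, 23.8 and 23.4 M reads lay behind libraries 1, 2 and 3, and 1 TPM on a transcript of 2 kb stood for 103, 86.5 and 91.4 reads. Nothing in the labels says that the libraries came from separate cultures, so the SD and the p-values measure only the spread between these libraries, which may be technical.

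The most abundant nuclear protein-coding genes included neuronal, glial and general ones. Stmn2, a growth-associated regulator of microtubules, stood at 1253 ± 35.8 TPM and Tmsb4x, which binds monomeric actin, at 1044 ± 30.5 TPM. The calmodulin gene Calm2 reached 999 ± 43.8 TPM. Apoe, a lipid carrier made mainly by astrocytes in the brain, reached 1024 ± 257 TPM, and the protease inhibitor gene Cst3 977 ± 309 TPM. On the longest coding transcript Apoe stood at 419.5 ± 113, Cst3 at 621 ± 139.8, Stmn2 at 687 ± 55.6, Tmsb4x at 755 ± 7.39 and Calm2 at 837 ± 47.5 TPM. Of the 25 highest protein-coding genes 6 were mitochondrially encoded, with mt-Nd1, a subunit of respiratory complex I, at 2574 ± 132 TPM. At a mean TPM of at least 1, 12344 of 27494 genes were detected, among them 11471 of 18221 protein-coding genes. Per library the number of detected genes was 12313, 12314 and 12394, a mean of 12340 ± 46.5. Of the detected protein-coding genes 444 stood at 100 TPM or more, 5201 between 10 and 100 and 5826 between 1 and 10. The 100 highest genes took 20.4% ± 0.336 of the summed gene values, and the mitochondrial genes 4.83% ± 0.0718. The mitochondrial share may be too low, because mt-Atp6, mt-Co2, mt-Co3 and mt-Nd3 were listed at 0. Library pairs correlated across detected genes with Pearson's r of 0.991, 0.987 and 0.987 on the log2(TPM + 1) scale; genes are not independent replicates. The median coefficient of variation of a detected gene was 9.09%.

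The first question was which topoisomerases these neurons transcribe. Top2b, whose product relaxes and untangles DNA in non-dividing cells, was the highest of the 8 topoisomerase genes in each library, at 68.8 ± 7.17 TPM. Top1, the type I enzyme that nicks a single strand, followed at 28.6 ± 2.44 TPM, and Top3b, which also acts on RNA, at 6.61 ± 0.375 TPM. Top2a, the type II enzyme of dividing cells, stood at 4.78 ± 0.513 TPM, and the mitochondrial Top1mt at 2.08 ± 0.191 TPM. Top3a, at 0.887 ± 0.208 TPM, and Gm960, at 0.802 ± 0.151 TPM, stayed below the detection limit, as did the meiotic Spo11, at 0.00583 ± 0.00606 TPM. Top2b (mm10 chromosome 14, 16365179 to 16430787, plus strand) exceeded Top2a (chromosome 11, 98992943 to 99024189, minus strand) by 3.59 ± 0.28 on the log2(TPM + 1) scale, in 3 of 3 libraries. It exceeded Top1 (chromosome 2, 160645888 to 160722764, plus strand) by 1.24 ± 0.03, also in 3 of 3 libraries. The exact two-sided sign-flip permutation test gave p = 0.25 for both, the smallest value that 3 libraries allow. The deposited sum of 1000000 is spread over rows that share reads, so levels and calls near the limit, such as those of Top3a and Gm960, rest on it: scaled to nuclear protein-coding genes, Top2b stood at 256.05 TPM and 14757 genes were detected. The size depends on the transcript row: on each gene's longest coding transcript Top2b stood at 41.03 ± 4.02 TPM and the differences were 3.03 ± 0.28 from Top2a and 0.51 ± 0.06 from Top1.

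**Figure D1:**
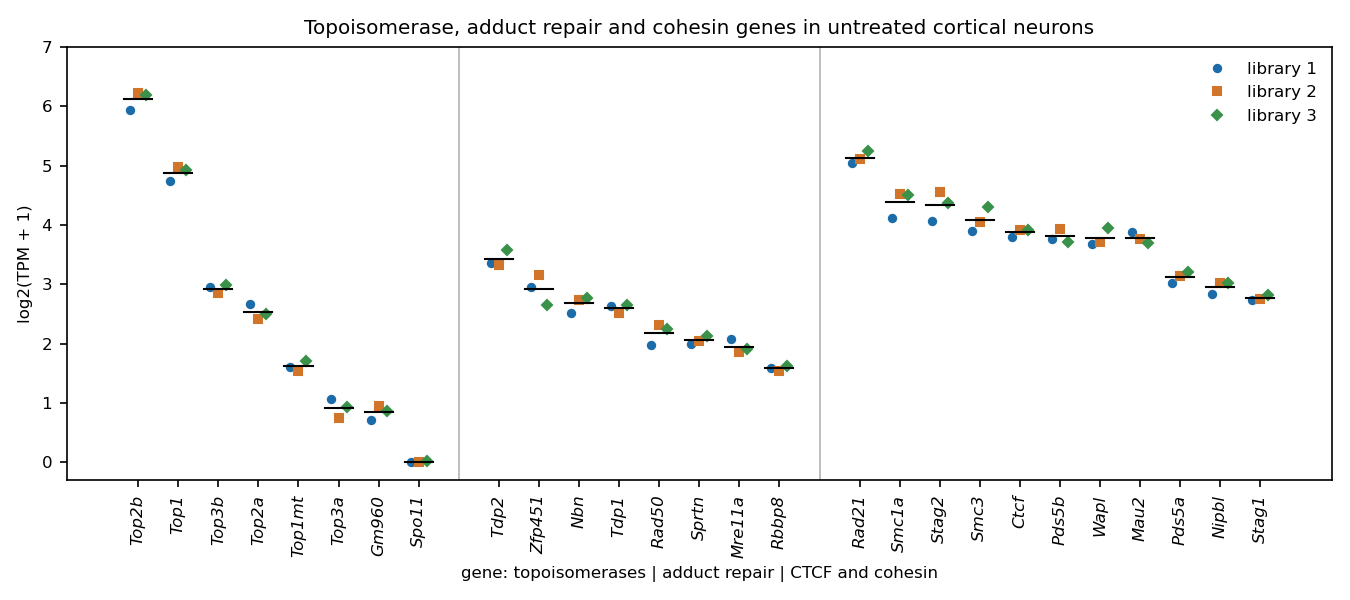
Levels of the topoisomerase, adduct repair and CTCF and cohesin genes, in log2(TPM + 1) on the vertical axis, with genes along the horizontal axis; each symbol is 1 of the 3 libraries and each bar their mean. Top2b and Top1 lie above the other topoisomerases in every library, and Rad21 is the highest of the CTCF and cohesin genes.

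Trapped topoisomerases leave protein adducts on DNA that must be removed before the break is sealed. All 8 measured members of the adduct repair list were detected, with a list median of 2.39 ± 0.08 on the log2 scale, at percentile 59.5 of random lists of protein-coding genes. Tdp2, which removes TOP2 from DNA ends, was the highest at 9.76 ± 1.07 TPM. Its counterpart for TOP1, Tdp1, stood at 5.05 ± 0.306 TPM, and the TOP2 cofactor gene Zfp451 at 6.65 ± 1.31 TPM, or 3.54 ± 0.848 TPM, below Tdp1, on the longest transcript. Mre11a, Rad50 and Nbn, which form the complex that processes broken ends, stood at 2.86 ± 0.308, 3.55 ± 0.5297 and 5.42 ± 0.586 TPM. Of the end-joining list 13 of 16 were detected (median 2.44 ± 0.05, percentile 63.7), led by Paxx at 30.3 ± 3.77, Parp1 at 22.6 ± 3.203 and Trp53bp1 at 21.8 ± 1.66 TPM. The kinase gene Prkdc was at 1.31 ± 0.171 TPM and Polq, of the alternative joining route, at 0.386 ± 0.0477 TPM. Of the homologous recombination list 4 of 13 were detected (median 0.67 ± 0.02, percentile 10.4). The median was 1.86 (percentile 21.9) with summed rows and 1.67 after scaling to nuclear protein-coding genes, both above the detection limit. Scaling raises all genes, however, and the list's percentile stayed at 10.4 with it. Rad52 was the highest gene of this list at 4.17 ± 0.189 TPM, and Brca1 and Brca2 stood at 0.961 ± 0.259 and 0.643 ± 0.0227 TPM. Tdp2 exceeded Tdp1 by 0.83 ± 0.11 on the log2 scale in 3 of 3 libraries (exact sign-flip p = 0.25), but the sum over transcript rows turned the sign.

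CTCF and cohesin anchor chromatin loops, and TOP2B is often found beside them. All 11 genes of that list were detected, with a median of 3.81 ± 0.07 at percentile 96.1. Rad21, the ring's closing subunit, stood at 34.2 ± 2.49 TPM and Smc1a and Smc3, which form its arms, at 20.1 ± 3.18 and 16.1 ± 2.49 TPM. Ctcf itself stood at 13.7 ± 0.6697 TPM, the loader gene Nipbl at 6.79 ± 0.588 TPM and the release factor gene Wapl at 12.8 ± 1.44 TPM. Stag2 exceeded its paralog Stag1 by 1.56 ± 0.24 on the log2 scale, in 3 of 3 libraries (exact sign-flip p = 0.25), and by 0.94 with summed rows. The RNA polymerase II elongation list had all 20 genes detected and a median of 3.94 ± 0.17, at percentile 99.6. Among its members Ssrp1, of the histone chaperone FACT, stood at 41.6 ± 5.24 TPM, Supt5 at 26.3 ± 0.3600 TPM and the kinase gene Cdk9 at 25.4 ± 6.54 TPM. The 18 chromatin remodeller and Polycomb genes, all detected, had a median of 3.495 ± 0.05 (percentile 96.5). Smarca2 and Smarca4, the alternative motors of the BAF complex, stood at 71.5 ± 4.87 and 27.1 ± 0.438 TPM, a log2 difference of 1.37 ± 0.11 that was 0.26 on the longest transcript and 3.04 with summed rows. Chd3, Chd4 and Chd5, alternative motors of the NuRD complex, stood at 55.7 ± 1.73, 28.3 ± 3.01 and 26.4 ± 4.27 TPM. Ezh1 and Ezh2, the paired Polycomb methyltransferases, differed by -0.10 ± 0.29 on the log2 scale, above 0 in 1 of 3 libraries (exact sign-flip p = 0.75), and by 0.29 on the longest transcript, so neither can be called the higher.

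The second question was which cells the cultures held. All 18 pan-neuronal genes were above 10 TPM and their median of 6.50 ± 0.12 lay above those of all 10000 random lists. Besides Stmn2, they included Gap43 of growth cones at 458 ± 8.95 TPM and the synaptic genes Syp and Snap25 at 451 ± 56.01 and 373 ± 27.2 TPM. Tubb3 stood at 234 ± 29.99 TPM and Map2, of dendrites, at 196 ± 14.5 TPM. Astrocyte genes were also high, with 14 of 15 detected and a median of 4.44 ± 0.12 at percentile 99.8. Sparcl1 stood at 341 ± 40.1 TPM, Aldoc at 266 ± 45.99 TPM (128 ± 21.4 TPM on the longest coding transcript), the glutamate transporter genes Slc1a3 and Slc1a2 at 184 ± 19.1 and 59.6 ± 5.45 TPM, and Gfap, the filament of reactive astrocytes, at 19.03 ± 3.88 TPM. The pan-neuronal median exceeded the astrocyte median by 2.07 ± 0.19 on the log2 scale in 3 of 3 libraries (exact sign-flip p = 0.25). Of the proliferation list 17 of 20 genes were detected but at low levels (median 1.45 ± 0.17, percentile 21.7). Pcna, the replication clamp, stood at 11.1 ± 1.35 TPM and Mki67 at 1.798 ± 0.384 TPM, and the pan-neuronal median was higher by 5.02 ± 0.29 in 3 of 3 libraries (exact sign-flip p = 0.25). Of the radial glia and progenitor list 12 of 14 were detected (median 2.06 ± 0.11, percentile 47.7). Only 1 member, Fabp7, stood at 100 TPM or more, at 419 ± 81.4 TPM, and these libraries do not tell which cells expressed it. Sox2 stood at 17.98 ± 3.38 TPM and Eomes, of intermediate progenitors, at 0.0129 ± 0.0173 TPM.

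Excitatory and inhibitory cortical neurons were both represented. Of the glutamatergic list 19 of 20 were detected (median 3.03 ± 0.16, percentile 87.6) and of the GABAergic list 16 of 18 (median 3.17 ± 0.14, percentile 90.8). Slc17a7 and Slc17a6, the vesicular glutamate transporter genes, stood at 89.98 ± 4.47 and 6.28 ± 1.23 TPM, a log2 difference of 3.66 ± 0.24 in 3 of 3 libraries (exact sign-flip p = 0.25). Layer markers spanned upper and deep layers, with Cux2 at 5.66 ± 0.635, Tbr1 at 7.203 ± 0.897 and Bcl11b at 4.32 ± 0.896 TPM. Gad1 and Gad2, which make GABA, stood at 91.03 ± 25.1 and 26.5 ± 6.92 TPM, the vesicular GABA transporter gene Slc32a1 at 21.7 ± 4.86 TPM and the neuropeptide gene Sst at 106 ± 25.9 TPM. Pvalb, which marks mature fast-spiking interneurons, was not detected at 0.267 ± 0.154 TPM. Taken within each library, the list medians differed by a mean of -0.03 ± 0.06, above 0 in 1 of 3 libraries. The medians printed above are of mean TPM, so their difference is not this value. The exact sign-flip test gave p = 0.5, where no p below 0.25 is possible, which does not show that the lists were equal. With list means or summed transcript rows the glutamatergic list was the higher, by 0.92 and 0.73.

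Markers of other cell types varied. The oligodendrocyte lineage had 9 of 14 genes detected (median 1.32 ± 0.28, percentile 22.1), of which 3 stood at 10 TPM or more. They were Olig1 at 34.4 ± 2.91 TPM, Olig2 at 15.95 ± 6.36 TPM and Pdgfra of precursor cells at 11.6 ± 6.73 TPM. The myelin genes Mbp and Mog stood at 1.51 ± 0.236 and 0.03304 ± 0.0313 TPM. Of the microglia list 3 of 14 were detected, none at 10 TPM or more (median 0.32 ± 0.10, percentile 3.39). The chemokine receptor gene Cx3cr1 was not detected, at 0.04502 ± 0.00402 TPM. Endothelial and mural genes had 3 of 14 detected (median 0.04 ± 0.01, percentile 0.1) and fibroblast and meningeal genes 4 of 12 (median 0.29 ± 0.10, percentile 3.41). Cajal-Retzius genes had 4 of 10 detected (median 0.13 ± 0.03, percentile 1.72). The Cajal-Retzius list nevertheless held Reln at 14.4 ± 4.499 TPM and Calb2 at 16.96 ± 0.323 TPM, both of which interneurons also express. Of the list for other neuron types 4 of 15 were detected, 1 of them at 10 TPM or more (median 0.32 ± 0.03, percentile 3.73). Slc6a3 of dopamine neurons was not detected, at 0.248 ± 0.0279 TPM. Ependymal and choroid plexus genes had a median of 1.07 ± 0.14 (percentile 19.1), with Ttr at 7.59 ± 2.71 TPM. None of the 7 measured blood genes was detected (median 0.04 ± 0.04, percentile 1.5), though the haemoglobin genes share sequence with their copies. In all, 12 of the 33 lists lay at or above the 95th percentile of random lists, 7 at or below the 5th and 14 between.

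**Figure D2:**
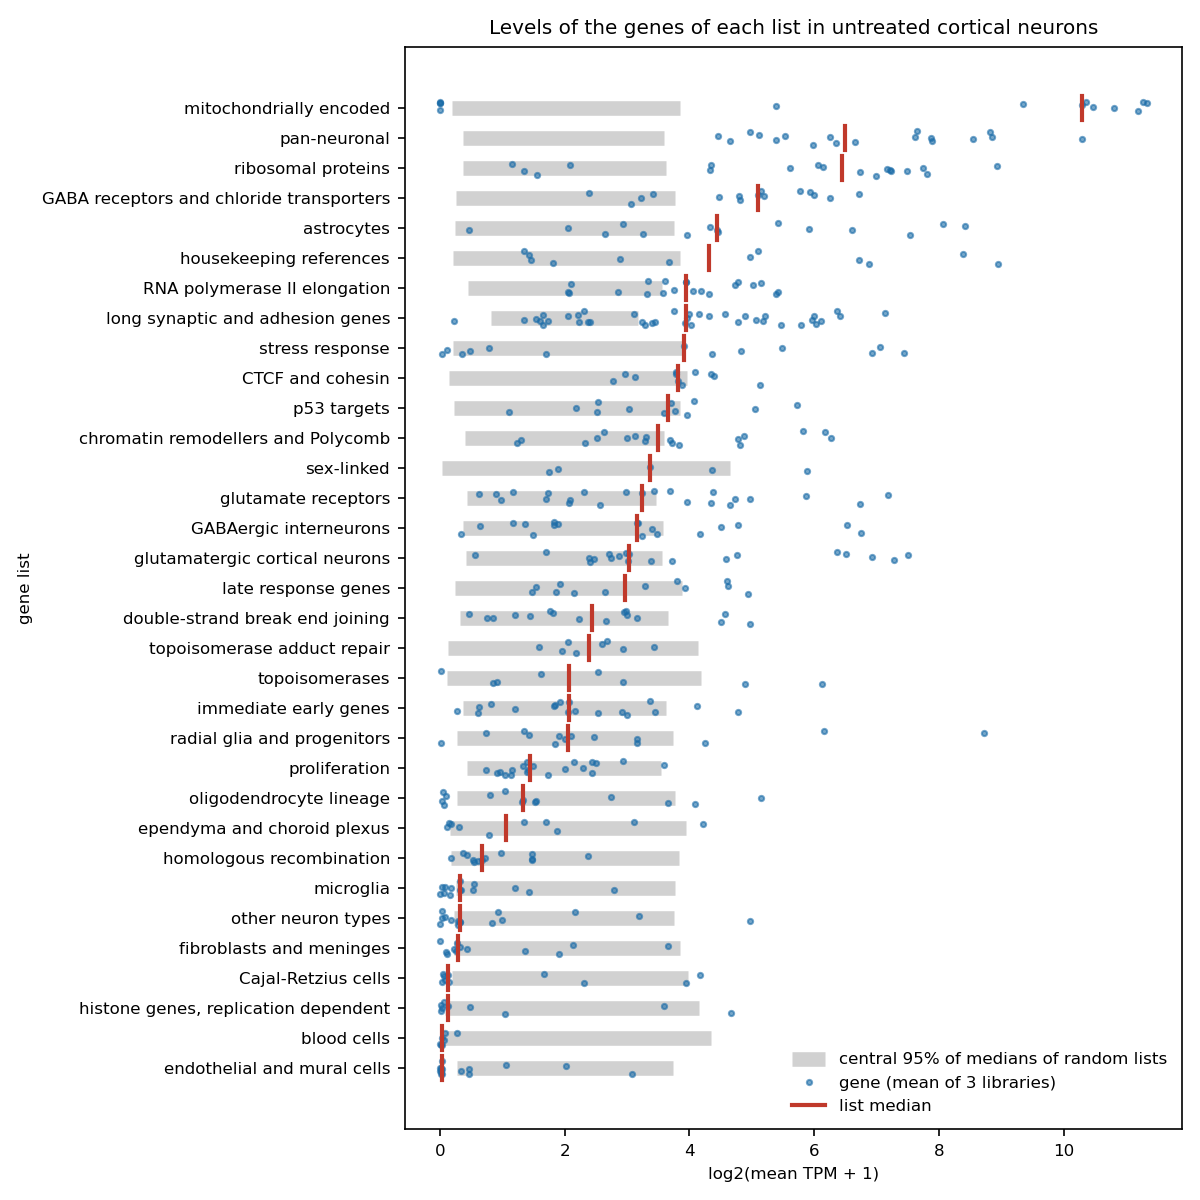
Levels of the genes of each of the 33 lists, in log2(mean TPM + 1) on the horizontal axis, with lists ordered by median on the vertical axis; points are genes, red bars list medians and grey bars the central 95% of the medians of 10000 random lists of the same size. The pan-neuronal median lies at 6.50 and the endothelial and mural median at 0.04.

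Fast transmission at cortical synapses rests on glutamate and GABA receptors, whose subunits change as neurons mature. All 15 genes of the GABA receptor and chloride transporter list were detected, and its median of 5.10 ± 0.13 also lay above those of all 10000 random lists. Gabra2 stood at 62.8 ± 8.26 TPM and Gabbr1, a metabotropic subunit, at 104 ± 13.5 TPM. Slc12a5, which extrudes chloride, exceeded Slc12a2, which imports it, by 1.59 ± 0.19 on the log2 scale in 3 of 3 libraries (exact sign-flip p = 0.25), and by 3.26 with summed rows. Of the glutamate receptor list 20 of 23 were detected (median 3.25 ± 0.04, percentile 94.3), and the percentile passed the 95th on the longest transcript (97.9), without library 1 (95.03) and with unique sequence (95.3). Gria2, the AMPA subunit that limits calcium entry, stood at 145 ± 7.81 TPM, above Gria1 by 1.32 on the log2 scale but by 0.33 on the longest transcript, and the obligate NMDA subunit gene Grin1 at 105 ± 5.49 TPM. Grin2b, the NMDA subunit of immature cortex, exceeded Grin2a, which replaces it with age, by 2.98 ± 0.09 in 3 of 3 libraries (exact sign-flip p = 0.25), at 14.5 ± 2.79 against 0.962 ± 0.2300 TPM, and by 3.73 with summed rows. These paralog pairs, with those of the repair and chromatin genes, were picked from the lists after their values were seen.

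Genes induced by neuronal activity were present at moderate levels. Of the immediate early list 14 of 18 were detected (median 2.06 ± 0.23, percentile 47.8), with the transcription factor genes Egr1 at 26.5 ± 4.304, Egr3 at 16.3 ± 3.85 and Fos at 7.002 ± 2.65 TPM. Npas4, induced by depolarisation, stood at 3.21 ± 0.822 TPM and Arc, of dendritic synapses, at 2.57 ± 0.528 TPM. All 12 late response genes were detected (median 2.97 ± 0.14, percentile 80.3), among them the scaffold gene Homer1 at 29.6 ± 2.68 TPM (6.297 ± 0.5304 TPM on the longest coding transcript) and the growth factor gene Bdnf at 5.29 ± 0.805 TPM. The p53 target list was detected in full (12 genes, median 3.65 ± 0.10, percentile 95.5), with Ccng1 at 51.6 ± 3.97, Bax at 32.1 ± 4.504, Cdkn1a at 14.6 ± 1.15 and Mdm2 at 12.6 ± 1.299 TPM. The stress list (median 3.92 ± 0.09, percentile 97.8) was split. The amino acid response genes Atf4 and Asns stood at 173 ± 9.25 and 120.0 ± 10.7 TPM and the endoplasmic reticulum chaperone gene Hspa5 at 133 ± 17.3 TPM, while the heat shock gene Hspb1, of which 48.4% of the words are unique, was at 0.0247 ± 0.0243 TPM and is uncertain. The percentile of the stress list fell to 76.8 and that of the p53 list to 90.1 with summed transcript rows, below the 95th. The p53 list also lay below it without library 3, at 93.7, and with the median of the libraries, at 93.4.

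The third question was how expression relates to gene length, since long neuronal genes are those most studied for their need of topoisomerases. Of 40 long synaptic and adhesion genes 39 were detected, with a median of 3.94 ± 0.18 at percentile 99.97. The cell adhesion gene Ntm stood at 139.7 ± 5.06 TPM, Dlg2 of the postsynaptic density at 81.1 ± 9.13 and Lsamp at 64.5 ± 3.09 TPM. Cntnap2 reached 28.7 ± 1.55 TPM (12.2 ± 1.51 TPM on the longest coding transcript), Auts2 12.5 ± 1.71, Csmd1 3.68 ± 0.349 and Lrp1b 2.13 ± 0.258 TPM, and Ctnna3 was the member not detected, at 0.1703 ± 0.0335 TPM. Among all 954 protein-coding genes over 200 kb the highest were App, the amyloid precursor gene, at 421 ± 25.3 TPM, the calcium sensor gene Syt1 at 236 ± 35.1 TPM, the calcineurin gene Ppp3ca at 205 ± 12.3 TPM, Map2, and Nell2 at 169 ± 8.75 TPM. The share of genes detected was 50.2% ± 0.186 under 10 kb, 64.8% ± 0.230 from 10 to 50 kb, 71.7% ± 0.394 from 50 to 100 kb, 72.8% ± 0.524 from 100 to 200 kb and 79.9% ± 0.744 over 200 kb. The median level of the shortest class was 1.03 ± 0.0307 TPM and that of the longest 5.60 ± 0.346 TPM. Across 18221 protein-coding genes Spearman's rho between span and TPM was 0.193 ± 0.00862 (n = 3 libraries), and 0.077 with the span of the highest transcript in place of that of the gene. Among the 11471 detected genes the sign turned, with a rho of -0.035 ± 0.0193, and detected genes over 200 kb had a median of 8.32 TPM against 9.80 TPM under 10 kb.

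**Figure D3:**
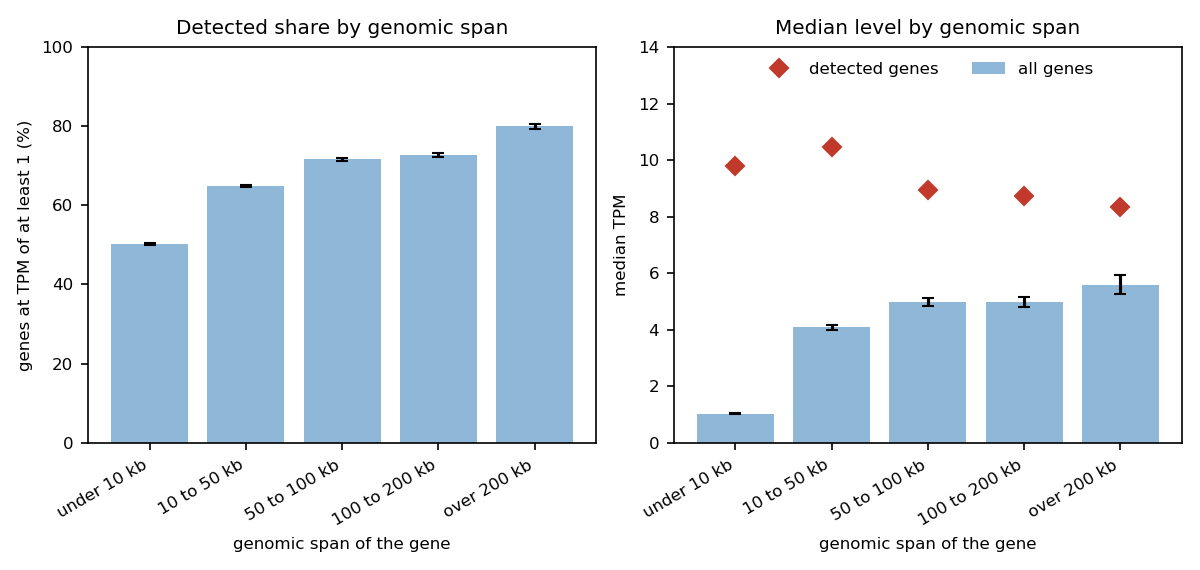
Protein-coding genes by genomic span on the horizontal axis, with the share at TPM of at least 1 in percent on the left and the median TPM on the right; bars are means of the 3 libraries, error bars their SD and diamonds the median of detected genes. The detected share goes from 50.2% under 10 kb to 79.9% over 200 kb, while the median of detected genes goes from 9.80 to 8.32 TPM.

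Genes with close copies elsewhere in the genome were listed at uneven levels and are uncertain. The ribosomal protein list had all 18 genes detected (median 6.44 ± 0.12, percentile 100), yet its members ranged from Rplp1 at 488 ± 44.7 TPM to Rps6 at 1.23 ± 0.211 TPM, although ribosomes need both. Of the housekeeping references (12 detected, median 4.32 ± 0.14, percentile 99.6), Actb stood at 495 ± 30.3 TPM and Hprt at 105 ± 2.39 TPM. Gapdh, a glycolytic enzyme gene with many pseudogenes, was at 2.498 ± 0.232 TPM, or 0.993 ± 0.277 TPM on the longest coding transcript, and 17.5% of its 50-base words occurred at no other annotated locus, against 100% for Hprt. The mitochondrially encoded list (median 10.29 ± 0.02, percentile 100) held mt-Co1 at 2462 ± 138 TPM but mt-Atp6, mt-Co2, mt-Co3 and mt-Nd3 were listed at 0 in libraries 1, 2 and 3. Replication-dependent histone genes, most of whose transcripts lack a poly-A tail, had a median of 0.12 ± 0.08 (percentile 3.5), but 1.04 (percentile 28.3) when only genes of unique sequence were used, so their low place is uncertain. Gm49450 stood at 1029 ± 191 TPM but overlaps the tubulin gene Tuba1a, at 678 ± 139 TPM, on the same strand, so the reads of the pair cannot be told apart. Among genes of long non-coding, antisense and processed-transcript types the highest were Rian and Meg3, both of an imprinted cluster, at 440.2 ± 20.3 and 326 ± 38.6 TPM. Gas5 stood at 165 ± 32.5 TPM and the nuclear RNA Malat1 at 99.8 ± 32.6 TPM. That order rests on the transcript row, since the longest transcripts gave 52.00 ± 2.38 TPM for Rian, 151 ± 19.3 for Meg3 and 32.2 ± 5.87 for Gas5, against 229.9 ± 71.5 TPM for Gm42418.

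A few genes differed between the libraries far more than the median coefficient of variation. Among genes of at least 10 TPM the largest coefficient of variation was that of Cwc22, a splicing factor gene, at 76.1%, with 8.35, 28.2 and 54.2 TPM in libraries 1, 2 and 3. The ribosomal gene Rpl26 followed with 69.2%, and Pdgfra with 57.9%. The sex-linked list (5 detected, median 3.36 ± 0.51, percentile 80.4) was also uneven. Xist, transcribed from the inactive X chromosome, stood at 28.5, 77.0 and 67.9 TPM in libraries 1, 2 and 3, and the Y-linked Eif2s3y at 27.7, 11.5 and 19.2 TPM. The highest transcript row of a gene carried a median of 28.4% ± 0.297 of the gene's summed TPM over 8593 detected genes with several rows, and 23.4% ± 0.854 for Top2b. Rows of a gene share reads, so these shares do not measure isoform use.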

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

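Signal outside the comparisons came from 3 sources, each given here as a value with no test and no explanation, and there were no control samples to set against them. The 1673 transcript rows without a matched gene held 2.005% ± 0.0461 of the summed TPM (SD, n = 3), and 1529 of them were above 0 in at least 1 library. The 1517 rows of small RNA genes, which poly-A selection should mostly leave out, held 1.07% ± 0.0505. A single one of them, Mir6236 (mm10 chromosome 9, 110281287 to 110281409), held 0.3499% ± 0.0579. Its 123 bases carried 21156, 15981 and 23242 reads in libraries 1, 2 and 3, or 3356, 3005 and 4136 TPM, where 3 reads, the limit that a count of 0 allows, would be 0.476, 0.564 and 0.534 TPM. It exceeded every protein-coding gene in each library, and it was picked out after its values were seen.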

How the results depend on the processing

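The longest transcript, unique sequence, nuclear genes and list means were chosen after seeing the data; the other settings were fixed before. The log2 differences of Top2b from Top2a (3.03 to 3.82) and from Top1 (0.51 to 1.62), and of pan-neuronal genes from astrocyte (1.85 to 2.52) and proliferation genes (4.87 to 5.86), kept their sign under every setting run. No sign-flip test could pass a threshold with 3 libraries. The glutamatergic minus GABAergic difference turned to 0.73 with summed rows and 0.92 with list means, Tdp2 minus Tdp1 to -0.13 with summed rows, and Ezh1 minus Ezh2 to 0.29 on the longest transcript and to 0.057 without replicate 3 (-0.235 to 0.057 when leaving out 1 library). The rank correlation of span and TPM turned to -0.035 among genes detected at 1 TPM, -0.021 at 0.5 and -0.080 at 5 (642 of the 998 protein-coding genes at 0 spanned under 10 kb), and was 0.077 with the span of the highest transcript, 0.240 with summed rows and 0.182 in genes with unique sequence. The share of the top 100 genes was 19.7% with summed rows, 21.7% on the longest transcript, 16.4% over nuclear protein-coding genes only and 17.3% over nuclear genes. The lowest replicate correlation was 0.992 with summed rows, 0.982 with a pseudocount of 0.1, 0.981 for genes above 5 TPM and 0.995 without a filter. The share of the highest row was 28.8% at a limit of 0.5 TPM and 27.1% at 5. The number of detected genes ran from 8294 at 5 TPM to 14757 after scaling, lists above the 95th percentile from 10 to 13 and lists below the 5th from 5 to 7. Except where stated, the cause was not tested. Of all values recomputed 355 were counted as kept, 123 as moved and 8 turned. Ratios and list differences counted as kept when the sign held, whatever their size. Other values had to stay within a set limit. Scaling and the pseudocount shift log values by construction, and they moved 32 and 22 of the list medians. The tally is therefore no measure of robustness. Reads per TPM limit low genes: under 1 TPM a short transcript rests on few reads.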

Other observations

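The library comparisons of this paragraph and the tests on Xist and the Y-linked genes were chosen after their values were seen, and the other tests were written before. The libraries differed in gene lists by more than random lists do. Of 99 values of a list in a library, set against the mean of the other 2 libraries, 38 lay outside the central 95% of random lists matched on expression. If all genes and values were independent, 4.95 would. Members of a list can vary together and the values of a list in the 3 libraries are tied, so this excess is not a test. In library 3 the immediate early genes were higher by a median of 0.40 on the log2 scale (16 of 18 members), with Fos at 9.96 TPM against 4.85 and 6.20 TPM in libraries 1 and 2. GABAergic genes were lower there, with a median of -0.34 and 4 of 18 members higher, and Sst stood at 79.7 TPM against 131 and 108 TPM. Other neuronal lists fell there as well: glutamatergic genes had a median of -0.14 (5 of 20 higher), glutamate receptors -0.18 (5 of 23) and long synaptic genes -0.10 (11 of 40). Stress genes were higher there too, by 0.12 (11 of 13 members). In library 2 the proliferation genes stood lower, with a median of -0.24 and 1 of 20 members higher, as did ribosomal protein genes (-0.22, 2 of 18 higher) and stress genes (-0.13, 4 of 13 higher). GABAergic (0.31, 15 of 18), pan-neuronal (0.14, 14 of 18) and long synaptic genes (0.18, 37 of 40) were higher in library 2. Library 1 deviated as well, with immediate early genes (-0.25, 2 of 18 higher) and long synaptic genes (-0.12, 8 of 40 higher) lower. The lower level of long synaptic genes was thus not particular to library 3. Proliferation genes (0.14, 17 of 20) and ribosomal protein genes (0.15, 13 of 18) were higher in library 1. Pdgfra, of oligodendrocyte precursors, stood at 11.5, 4.96 and 18.4 TPM in libraries 1, 2 and 3. The libraries have no labels that set them apart.

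Astrocyte genes were lower in library 1, with a median of -0.17 on the log2 scale and 4 of 15 members higher. In library 3 astrocyte genes were higher by a median of 0.20 on the log2 scale and pan-neuronal genes lower, with a median of -0.15. A larger share of astroglial RNA was tested on a second list of 29 astroglial genes, none of them in another list here: of its 28 detected members 13, or 46.4% (exact 95% interval 27.5 to 66.1%), were higher in library 3, with a median of -0.01, against 50.0% of all detected genes. By the rule written beforehand, a share under 50% counted against this explanation, and 46.4% was under it. The interval spans 50%, but the rule for using the interval was settled after the value was seen. Radial glia genes (0.19, 10 of 14 higher) and oligodendrocyte genes (0.09, 10 of 14 higher) go with the explanation. So do Apoe (899.7, 853 and 1320.2 TPM in libraries 1, 2 and 3) and Cst3 (805, 791 and 1334 TPM). These genes were not part of the written rule, and the explanation is not settled. A trend with transcript length, span and GC content explained 5.64% of the variance of the deviations, and its removal left 99.9% of the astrocyte minus pan-neuronal difference, 0.36 before and after, which argues against that trend as the cause. The labels give no second group, so no biological difference named by the design was tested.

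Xist and the Y-linked genes moved in opposite directions between libraries. All 4 Y-linked genes (Ddx3y, Uty, Kdm5d and Eif2s3y) were highest in library 1, which had the lowest Xist level, and lowest in library 2, which had the highest. Their median log2 difference between these libraries was 0.89 and that of Xist -1.40, and a factor shared by all genes cannot move them in opposite directions, which argues against library scaling as the cause. A candidate explanation is that the cultures held cells of male and female embryos in different shares. The labels give no sex, so this remains a hypothesis found and tested on the same 4 genes.

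Ribosomal protein genes were listed at very uneven levels, 27 of 83 under 5 TPM and 17 at 100 TPM or more, and 4 mitochondrial genes at 0. Across the 83 genes the share of 50-base words found at no other annotated locus correlated with log2(TPM + 1). Spearman's rho was 0.381 (permutation p = 0.00048), though genes are not independent replicates. Exonic length gave -0.129 (permutation p = 0.248), where a loss of short transcripts was predicted to give a positive rho. The length is that of the highest row, often a short model, which lowers this rho either way. For Rps15a, that row of 250 bases stood at 217.6 TPM, against 21.6 TPM on the longest transcript. The test therefore cannot decide on a loss of short transcripts. The mitochondrial genes listed at 0 had at most 2.01% such words and the 7 detected ones at least 37.8%. This is consistent with reads from shared sequence having been left out of the counts, so low values of such genes may not be low expression. Exceptions remain: Rplp1, with 40% such words, was at 488 TPM, and Rpl34, with 93.1%, at 1.12 TPM.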
